A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

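RNA of methanol-treated and untreated budding yeast (Saccharomyces cerevisiae strain S288C, a haploid laboratory strain of mating type alpha) was compared on 2-colour spotted arrays. Per the labels' protocols, exponentially growing cultures in rich glucose medium at 25 °C received methanol to 5% at an optical density of 1 and were harvested after 2 h, and control cultures grew for the same 2 h without it. Poly(A) RNA was copied into cDNA labelled with Cy5 for the treated and Cy3 for the untreated culture. The series held 3 arrays of independent biological samples, numbered 1 to 3, and each array was scanned at high and at low laser power, which gave 6 scans. Per the labels, the scan at low power was meant for spots too bright for the scanner's range. Both scans of an array hold the same RNA pair and counted as 1 replicate. The dyes were not swapped on any array, so a gene-specific dye effect stays in every ratio.

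The deposited values are log ratios, 1 column per scan. Per the labels, the authors ran a LOWESS normalization on the spots with flag 0, and merged the scans of an array in GeneSpring; the merged value is not analysed here. Spots without a value in a scan were taken as flagged out. The deposited values carry no statement of their log base or direction: they were read as log2 and, since the treated sample is the Cy5 channel and is given as channel 1, as likely methanol over untreated. If the base were another, the fold values would change and the tests would not. If the direction were the opposite, every sign would turn. The medians of the 6 scans lay between −0.03 and 0.01. No spot intensities were used, so no background correction, dim-spot filter or signal over background could be computed, and the number of scans with a value served as a rough measure of brightness. On replicates 1, 2 and 3, 2650, 2882 and 2300 spots had a value at high power only, and 90, 49 and 92 at low power only. The latter may be too bright for the high-power scan. Genes with few scans may thus include some very bright ones, so matching on scans is not a full match on brightness.

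The arrays held 6912 spots. The platform annotation gave 1 gene for 5446 spots, several genes for 0 and none for 1466. The 5446 identifiers all matched the R64 reference gene table, which was used for names and gene order. No genome build came with the values, so no coordinates are given. The named spots covered 5379 genes, of which 20 had several spots. Their spots were averaged on the log2 scale. The 49 spots of ACT1 carried identical copies of the same value, as did the pairs of GEX1 and YBR012W-A, and each set counted once. Spots of a gene differed most for PRM7 (−0.17 and 2.04) and MMS4 (−0.01 and 1.23). High-power scans gave values for 5621, 4714 and 5842 spots on replicates 1, 2 and 3, and low-power scans for 3061, 1881 and 3634. Across spots with both values, Pearson's r between the scans of an array was 0.961, 0.962 and 0.952, where spots are not independent replicates.

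For each spot the mean of the available scans was taken, spots were averaged per gene, and each array was centred on its median gene. The medians before centring were −0.05, −0.05 and −0.02. Genes with a value on all 3 arrays (4336) were tested with limma 3.58.1 in R 4.3.3, as an intercept against 0 with empirical Bayes moderation, and called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p for a gene comes from this limma fit. The scans were compared by the same fit on the per-spot difference of high minus low power within each array, averaged per gene, less the difference of the scans' medians. Before the data were examined, 59 gene lists were fixed, of which 56 had at least 4 measured members. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Lists share members, so their calls are not independent. The genes named are the 12 highest and the 12 lowest called genes with the same sign on all arrays, all measured members of the formaldehyde list, and for each called list the 4 called members with the largest change in its direction. Other genes named were chosen after their values were seen.

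Tested on simulated data (4336 genes, 200 of them changed, 10 simulations), the fit recovered 72.7% of genes changed 1.5-fold, 99.4% of those changed 2-fold and 100% of those changed 3-fold. Of its calls in these simulations, 8.39% were false, above the nominal rate, and 1 of 560 tests of lists without change was called. In the data 50.3% of genes were called, far more than were changed in the simulations. The cut-off on p that the adjustment sets was therefore more lenient in the data, and the simulated rates may not carry over. The simulated genes were independent of each other, whereas the estimated correlation of the ribosomal protein list was 0.46. The simulation therefore cannot tell how often correlated lists without change would be called. The number of arrays, 3, limits the precision, and an exact sign-flip test of a single gene on 3 arrays could not give a p below 0.25. Alternatives fixed before the data were examined were either scan alone, no centring, scale or quantile normalization between arrays, values on at least 2 arrays, leaving out genes whose scans differ by over 0.5, robust moderation, array weights, an adjusted p under 0.01, leaving out each replicate, and a ribosomal protein list without the B copy of each pair. A correction for the position of the spot, by subtracting the median of each of 24 levels of a field of the spot number, was added after seeing the data, as was the difference of gene means in place of that per spot. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read and joined the values, and matplotlib 3.10.9 drew the plots. The 1466 spots without a gene name entered no gene or list test.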

Results

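The data were log2 ratios of transcript levels in yeast exposed to 5% methanol for 2 h over those in untreated cultures, from 3 arrays of independent cultures. The series has a single condition, and the comparison asks which transcripts differ after growth with this toxic solvent. Ratios are signed as methanol over untreated. That direction is likely rather than stated with the values, as it rests on the treated RNA being in the Cy5 channel, and the log base was taken as 2. Values are means ± SD over n = 3 arrays. Of the 5379 genes on the array, 5166, 4399 and 5339 had a value on replicates 1, 2 and 3.

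Among fixed gene lists, those of the general stress response, hexose transport and the cell wall were called higher in methanol, and those of ribosome biogenesis, translation factors and purine, histidine and aromatic amino acid synthesis were called lower. Each of these list calls had an adjusted p = 0.344 with an estimated correlation and so did not hold there, in a test with little power on 3 arrays. Of 4336 genes tested, 1129 were higher and 1051 lower at limma's adjusted p, and of these 327 rose and 244 fell at least 2-fold. The largest rise was that of RCK1 (YGL158W), a protein kinase gene of the oxidative stress response, at a log2 ratio of 4.59 ± 0.43 (limma adjusted p = 1.25e-05). HSP26 (YBR072W), a small heat shock protein gene, rose 14.8-fold (3.89 ± 0.29), and DDR2 (YOL052C-A), a stress-induced gene, rose 11.9-fold (3.57 ± 0.04). The largest fall was that of EEB1 (YPL095C), which encodes an enzyme of fatty acid ethyl ester synthesis, at −2.85 ± 0.40, or 0.139 times the untreated level.

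The 12 highest genes also held JEN1 (YKL217W), a lactate and pyruvate transporter gene, at 3.48 ± 0.47, and GRE1 (3.30 ± 0.19) and SIP18 (2.97 ± 0.25), which encode hydrophilins, proteins linked to desiccation stress. FAT3, a gene of fatty acid uptake, rose by 3.27 ± 0.25, GND2, the minor isoform of an enzyme of the pentose phosphate pathway, by 3.16 ± 0.70, and FIT3, a cell wall protein gene of siderophore iron uptake, by 3.10 ± 1.21. FIT3 had values at high power only on replicates 1 and 2 and at low power only on replicate 3, so its spread mixes array and laser power. YDL218W (3.62 ± 0.20), CPP3 (3.32 ± 0.21) and YNL195C (3.31 ± 0.10) complete that group. RCK1, HSP26, YDL218W, GRE1 and SIP18 had values at high power only. Below EEB1 stood MF(ALPHA)2, a gene of the alpha mating pheromone (−2.41 ± 0.10), TIF3, the gene of translation initiation factor 4B (−2.16 ± 0.24), HRI1 (−2.14 ± 0.24) and YHB1, the flavohaemoglobin gene (−2.10 ± 0.21). HIS1 (−2.07 ± 0.09), GDH1 (−2.02 ± 0.11) and ASN1 (−2.02 ± 0.07) encode enzymes of histidine, glutamate and asparagine synthesis. RPA49 (−1.97 ± 0.35), GUA1 (−1.95 ± 0.20), AQR1 (−1.94 ± 0.29) and NSR1 (−1.93 ± 0.37) encode a subunit of RNA polymerase I, GMP synthase, a plasma membrane transporter and nucleolin. These 24 genes were chosen to have the same sign on all 3 arrays. Of the 2180 called genes 2178 had it, and so did 72.4% of all genes tested, against 25% by chance.

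**Figure D1:**
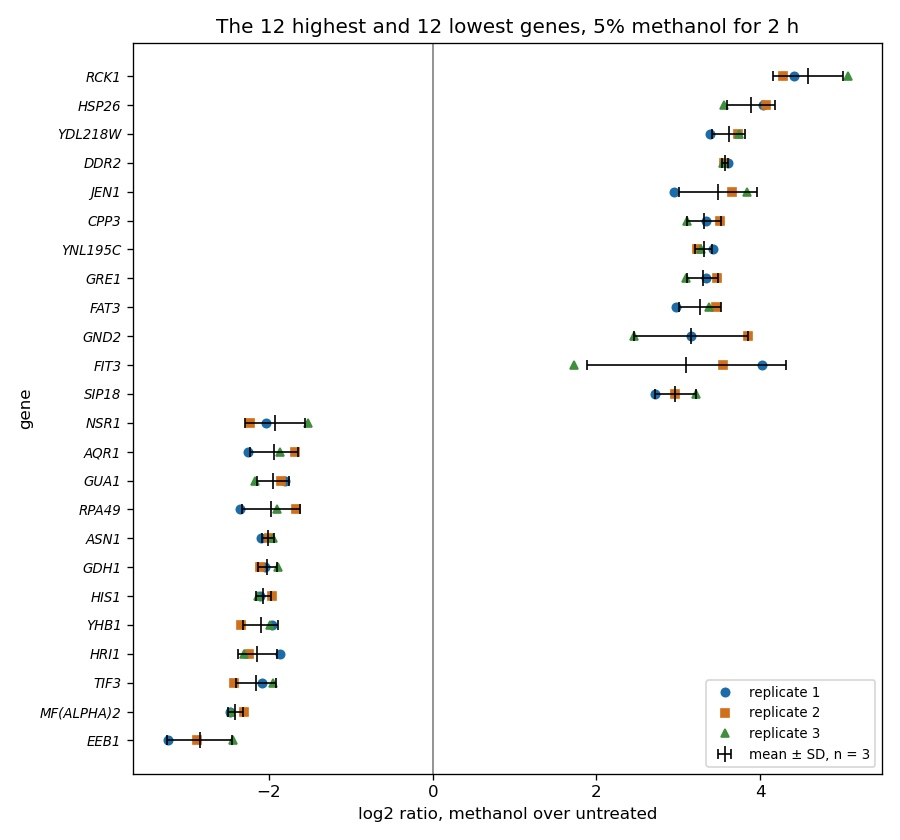
Log2 ratio of methanol over untreated (x axis) for the 12 highest and 12 lowest called genes (y axis), with a symbol per replicate array and black bars for the mean ± SD over n = 3 arrays. The means run from 4.59 for RCK1 to −2.85 for EEB1, and FIT3 has the widest spread, at an SD of 1.21. Its value is from the low-power scan on replicate 3 and from the high-power scan on replicates 1 and 2.

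Of 56 gene lists tested, 20 were higher and 13 lower by limma's camera with its preset correlation. No call held when the correlation was estimated from the arrays, where the adjusted p of the called lists ran from 0.344 to 0.606. That estimate rests on 3 arrays, which leaves the test little power. General stress and histidine synthesis also had 0.344, with estimated correlations of −0.02 and −0.11. A lost call there thus decides neither for nor against a list. With fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, 24 lists were higher and 14 lower. In the counts of members below, those adjusted over the list alone were the same unless they are given. Medians under either scan alone cover only the members valued in that scan on all 3 arrays, so they may not be over the same genes.

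The general stress list, targets of the transcription factors Msn2 and Msn4, had 32 of 33 measured members higher, 0 lower and a median log2 ratio of 1.61 (camera adjusted p = 8.58e-16, and adjusted p = 0.344 with an estimated correlation). Beside DDR2, GRE1 and GND2, PHM7 rose by 2.95 ± 0.30, and PNC1 alone did not pass the test. Of 22 genes of trehalose and glycogen metabolism 15 rose, with IGD1 at 1.88 ± 0.12, GPH1, the glycogen phosphorylase gene, at 1.57 ± 0.20, ATH1 at 1.33 ± 0.13 and GLC3 at 1.07 ± 0.11. In that list 0 fell over all genes and 1 fell when adjusted over the list alone. Redox defence genes rose in 15 and fell in 3 of 30 cases (17 and 4 adjusted over the list alone), with a median of 0.53, or 0.32 with the low-power scans alone. OYE3 (1.83 ± 0.14), TSA2 (1.83 ± 0.24), a peroxiredoxin gene, the catalase gene CTT1 (1.79 ± 0.06) and GTT1 (1.5 ± 0.15) led the rises, while GPX2 (−1.67 ± 0.38), GSH2 (−0.87 ± 0.18) and TRR1 (−0.56 ± 0.20) fell. For both lists the adjusted p was 0.344 with an estimated correlation. Heat shock chaperones went both ways, with 6 of 27 higher, 8 lower and a median of −0.08 against a mean of 0.02, and the list was not called (camera adjusted p = 0.544). In it HSP26 rose while the Hsp90 genes HSC82 (−1.21 ± 0.28) and HSP82 (−1.0 ± 0.29) fell.

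Lists of carbon source use were called higher. Of 13 genes of the glyoxylate cycle and gluconeogenesis 11 rose (median 1.36), with JEN1 above, FBP1, the fructose bisphosphatase gene, at 2.22 ± 0.35, ADY2 at 2.20 ± 0.30 and SIP4 at 1.64 ± 0.10, and 2 of the 13 had a value in all 6 scans. Of 18 genes on a list of hexose transporters and their regulators, 15 rose (median 1.40). The transporter genes HXT5 (2.88 ± 0.20), HXT7 (2.02 ± 0.44), HXT16 (1.99 ± 0.30) and HXT13 (1.92 ± 0.39) led, and signals of near-identical transporters may be shared. Genes of galactose, maltose and sucrose use rose in 11 of 14 cases (median 0.80), with the invertase gene SUC2 at 2.18 ± 0.49, GAL3 at 1.88 ± 0.51, MAL12 at 1.56 ± 0.34 and GAL10 at 1.18 ± 0.33. For these 3 lists the adjusted p was 0.344 with an estimated correlation.

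Genes of peroxisomal fatty acid oxidation rose in 11 of 20 cases (median 0.52), among them the carnitine carrier and transferase genes CRC1 (2.22 ± 0.52) and CAT2 (2.09 ± 0.23), POX1 (1.98 ± 0.16) and TES1 (0.96 ± 0.10), but the median was 0.07 and the list not called with the low-power scans alone (adjusted p = 0.573). The citric acid cycle list had 8 of 15 members higher and 1 lower (median 0.52). SDH4 (1.41 ± 0.13), SDH1 (1.04 ± 0.18), FUM1 (0.82 ± 0.19) and LSC1 (0.81 ± 0.29) rose and IDH2 fell by 0.48 ± 0.13. Respiratory chain and ATP synthase genes rose in 15 and fell in 3 of 33 cases (median 0.27, camera adjusted p = 0.0469), with NDE2 at 2.07 ± 0.17, ATP15 at 1.31 ± 0.15, COX9 at 1.22 ± 0.09 and ATP18 at 1.1 ± 0.32. These lists had an adjusted p = 0.359, 0.344 and 0.480 with an estimated correlation. The respiratory list was no longer called without replicate 1 (adjusted p = 0.0551), without replicate 3 (0.0912), without centring (0.0506), without genes whose scans differ (0.0603) and after the position correction (0.123), with medians of 0.31, 0.25, 0.23, 0.27 and 0.24.

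All 5 measured aldehyde dehydrogenase genes rose (median 1.90), with ALD4 at 2.35 ± 0.33, ALD3 at 1.95 ± 0.27, ALD2 at 1.90 ± 0.21 and ALD6 at 1.18 ± 0.47. All 5 measured aryl-alcohol dehydrogenase genes, a family of similar sequences, rose too (median 1.00), with AAD10 at 1.64 ± 0.05, AAD6 at 1.24 ± 0.23, AAD4 at 1.00 ± 0.60 and AAD14 at 0.78 ± 0.26. Without replicate 2 the median of that list, which is AAD4, was 0.65. The adjusted p was 0.379 and 0.464 with an estimated correlation. Of the genes that oxidise formaldehyde and formate, FDH2, a formate dehydrogenase gene, rose by 0.84 ± 0.12 (limma adjusted p = 0.00151) and YJL068C, the S-formylglutathione hydrolase gene, by 0.68 ± 0.12 (limma adjusted p = 0.00369). SFA1, the gene of the formaldehyde dehydrogenase, stood at 0.29 ± 0.41 and did not pass the test (limma adjusted p = 0.190). FDH1 had values of 0.74 and 0.53 on replicates 1 and 3, before centring, and none on replicate 2, so it was not tested, and the 3 measured members were too few for a list test. FDH1 and FDH2 are near-identical and may share signal. Alcohol dehydrogenases rose in 5 and fell in 1 of 10 cases (median 0.46), and the list was not called (camera adjusted p = 0.0619).

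Cell wall genes rose in 17 and fell in 1 of 24 cases (median 0.71, and 0.43 with the high-power scans alone). TIP1 (1.80 ± 0.20), PIR3 (1.80 ± 0.14), CWP1 (1.66 ± 0.04) and YPS1 (1.5 ± 0.05) rose, and PIR1 fell by 0.75 ± 0.07. In the seripauperin list, a family of near-identical cell wall genes that may share signal between members, 18 of 21 genes rose (19 adjusted over the list alone), with a median of 0.91 and examples PAU2 (1.35 ± 0.27), PAU5 (1.28 ± 0.29), PAU23 (1.24 ± 0.19) and PAU24 (1.22 ± 0.25). Both lists had an adjusted p = 0.344 with an estimated correlation. Thiamine and pyridoxine genes rose in 12 and fell in 3 of 16 cases (median 0.59). Over the members valued in the low-power scans alone, the median of that list was −0.057 (adjusted p = 0.816). SNZ1 rose by 1.91 ± 0.11, and THI12 (1.86 ± 0.20), THI11 (1.82 ± 0.21) and THI13 (1.82 ± 0.15) are near-identical copies. Iron regulon genes rose in 12 and fell in 3 of 27 cases (median 0.33, and 13 and 3 adjusted over the list alone), with FIT3 above, FIT2 at 2.59 ± 0.86, FIT1 at 2.05 ± 0.57 and the haem oxygenase gene HMX1 at 1.18 ± 0.16. The reductase gene FRE1 fell by 1.5 ± 0.57. Without replicate 3 the median of the iron list was 0.51, and with fry that list was not called (adjusted p = 0.0955). The thiamine and iron lists had an adjusted p = 0.464 and 0.606 with an estimated correlation.

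Of the other lists, 5 were called higher. Genes for poor nitrogen sources rose in 13 and fell in 2 of 22 cases (median 0.56, and 0.07 with the low-power scans alone, where it was not called; 14 and 2 adjusted over the list alone), with DAL1 at 2.07 ± 0.52, the amino acid permease genes GAP1 at 1.46 ± 0.28 and DIP5 at 1.35 ± 0.53, and UGA4 at 1.34 ± 0.19, whereas GDH1 fell. DNA damage genes rose in 7 of 13 cases (median 0.53, and 0.31 with values on at least 2 arrays), with REV1 at 1.32 ± 0.44, HUG1 at 1.28 ± 0.13, DDI2 at 0.84 ± 0.08 and TSL1, which is better known as a gene of trehalose synthesis, at 0.80 ± 0.15. Meiosis genes rose in 10 of 13 cases (median 0.51), with REC114 at 1.89 ± 0.19, SPR1 at 1.35 ± 0.31, DMC1 at 1.17 ± 0.48 and DIT1 at 0.94 ± 0.46. They are genes of sporulating diploids, whereas the strain is haploid. Of 32 on the array 13 were measured, with a median of 3 scans with a value. Their median lay above 98% of 10000 random lists of genes with as many scans. Spots without a gene name had a median of 0.43, so a lean of dim spots to higher ratios stays open. The multidrug resistance list held targets of the regulators Pdr1, Pdr3 and Yrr1 as well as drug pumps, so not all members are pumps. Its genes rose in 9 and fell in 1 of 18 cases (median 0.39, and 11 and 1 adjusted over the list alone), with PDR11 at 1.11 ± 0.04, RTA1 at 1.01 ± 0.38, TPO3 at 0.84 ± 0.37 and FLR1 at 0.74 ± 0.35. That list was not called without replicate 2 (adjusted p = 0.0863), with array weights (0.0542) or with fry (0.056). Autophagy genes rose in 8 of 18 cases (median 0.25, and 0.44 without replicate 2), with ATG22 at 1.58 ± 0.44, ATG33 at 1.32 ± 0.23, ATG40 at 0.99 ± 0.02 and ATG8 at 0.71 ± 0.61. ATG8 stood at 0.37 without replicate 1 and lost its call there and without replicate 3. In this order, the 5 lists had an adjusted p = 0.464, 0.344, 0.463, 0.50 and 0.344 with an estimated correlation.

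**Figure D2:**
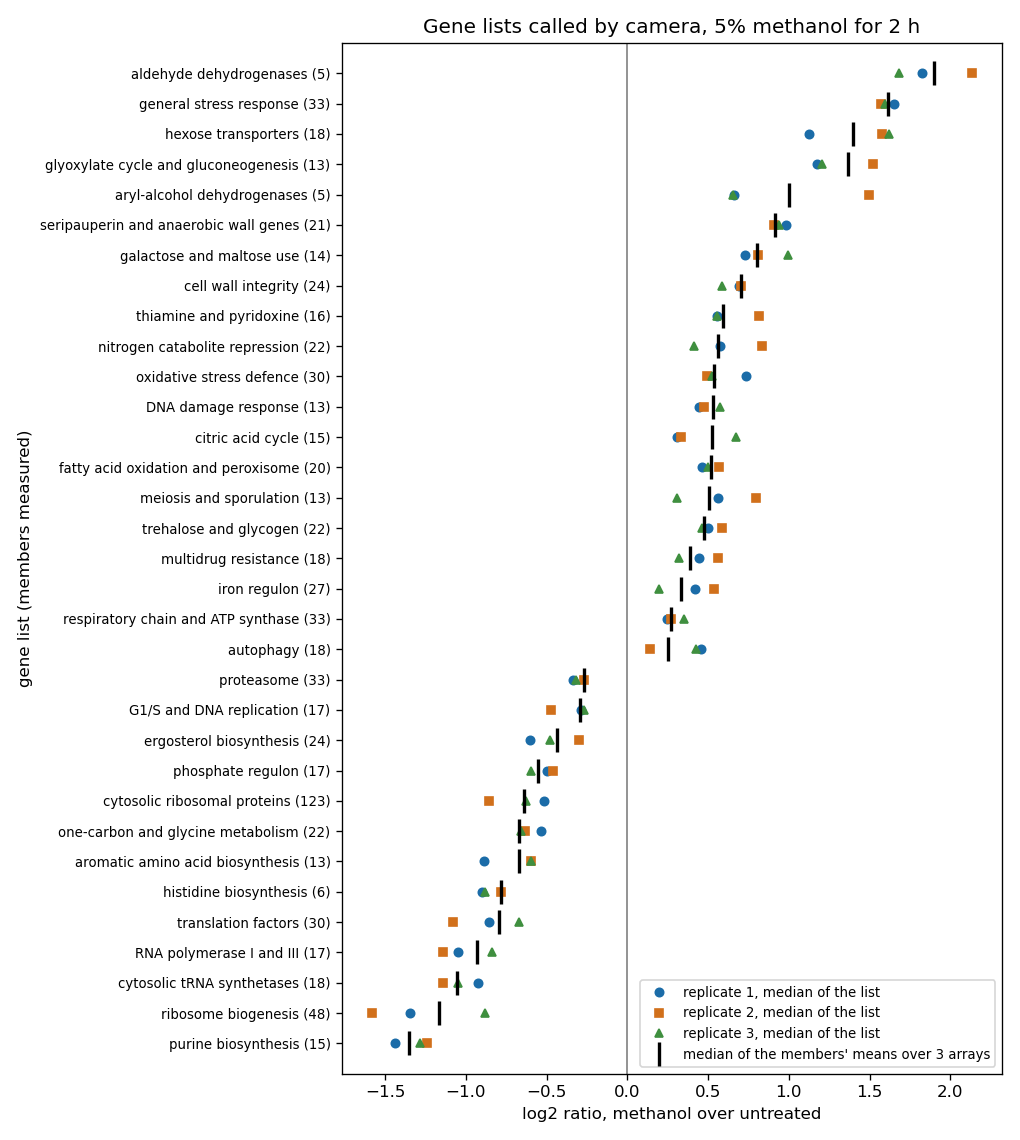
Median log2 ratio of methanol over untreated (x axis) of each of the 33 gene lists called by camera (y axis, with the number of members measured), with a symbol for the list's median on each of the 3 arrays and a black tick for the median of the members' means. The ticks run from 1.90 for the aldehyde dehydrogenases to −1.35 for purine biosynthesis.

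Lists of cytosolic ribosomal proteins, ribosome biogenesis and translation were called lower. Of the genes of cytosolic ribosomal proteins, 94 fell, 0 rose and 29 did not pass the test (97 fell and 1 rose adjusted over the list alone), with a median of −0.64. RPS6B stood at −1.77 ± 1.41, which rests on replicate 2 and was −0.95 without it, and RPS6A (−1.57 ± 0.25), RPS20 (−1.40 ± 0.21) and RPS3 (−1.28 ± 0.31) followed; many of these genes are near-identical pairs. Ribosome biogenesis genes fell in 37 and rose in 1 of 48 cases (39 and 1 adjusted over the list alone), with a median of −1.17 and NSR1, CBF5 (−1.84 ± 0.10), NOP58 (−1.82 ± 0.39) and NHP2 (−1.78 ± 0.61) as the largest falls. Of 17 genes of RNA polymerases I and III, 14 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of −0.93. RPA190 fell by 1.79 ± 0.32, RPA43 by 1.43 ± 0.33 and RPC53 by 1.45 ± 0.85, the last being −0.96 without replicate 1. Aminoacyl-tRNA synthetase genes fell in 17 of 18 cases (median −1.06), among them MES1 (−1.90 ± 0.11), WRS1 (−1.76 ± 0.13), KRS1 (−1.65 ± 0.30) and FRS1 (−1.44 ± 0.35). Of 30 genes of translation factors, 23 fell (24 adjusted over the list alone), with a median of −0.80 and TIF3, YEF3 (−1.48 ± 0.14), TIF5 (−1.46 ± 0.11) and NIP1 (−1.40 ± 0.18) lowest. The adjusted p was 0.464 for ribosomal proteins and 0.344 for the other 4 lists with an estimated correlation.

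Purine synthesis held the largest median fall of any list, −1.35, with 13 of 15 genes lower. Beside GUA1, the adenine deaminase gene AAH1 fell by 1.86 ± 0.90, IMD3 by 1.83 ± 0.21 and HPT1 by 1.81 ± 0.33. Histidine synthesis genes fell in 5 of 6 cases (median −0.78), with HIS1 above, HIS6 at −1.38 ± 0.07, HIS4 at −0.94 ± 0.13 and HIS5 at −0.63 ± 0.34, and HIS5 lost its call without replicate 1 or 3. Aromatic amino acid genes fell in 9 of 13 cases (median −0.67), with ARO7 at −1.87 ± 0.21, TRP3 at −1.30 ± 0.11, TYR1 at −1.11 ± 0.17 and ARO9 at −1.01 ± 0.06. Genes of folate-bound carbon units, serine and glycine fell in 15 and rose in 2 of 22 cases (median −0.67). SER2 fell by 1.63 ± 0.11, MTD1 by 1.36 ± 0.09, SER1 by 1.18 ± 0.07 and MIS1 by 0.98 ± 0.07, while MET13 (1.12 ± 0.14) and SHM1 (0.58 ± 0.09) rose. Each of these 4 lists had an adjusted p = 0.344 with an estimated correlation.

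Ergosterol genes fell in 13 and rose in 1 of 24 cases (14 and 1 adjusted over the list alone; median −0.43). ERG25 fell by 1.58 ± 0.22, CYB5 by 1.42 ± 0.38, ERG11 by 1.38 ± 0.21 and ERG2 by 1.27 ± 0.24. The phosphate regulon fell in 11 and rose in 2 of 17 cases (median −0.56), with the acid phosphatase genes PHO11 (−1.31 ± 0.16), PHO12 (−1.15 ± 0.08) and PHO3 (−0.82 ± 0.33) and the polyphosphate gene VTC3 (−1.0 ± 0.05) lower. The phosphate transporter gene PHO89 (1.79 ± 0.37) and GIT1 (1.68 ± 0.27) rose. Genes of the G1/S transition and DNA replication fell in 7 of 17 cases (median −0.29), with POL30 at −1.12 ± 0.19, RNR1 at −1.12 ± 0.34, MNN1 at −1.06 ± 0.23 and POL1 at −0.77 ± 0.37. Proteasome genes fell in 13 and rose in 1 of 33 cases (12 and 1 adjusted over the list alone; median −0.27), with RPN9 at −0.86 ± 0.07, RPN8 at −0.85 ± 0.40, RPN11 at −0.84 ± 0.05 and RPT4 at −0.68 ± 0.20. POL1 and RPN8 lost their calls without replicate 1 (limma adjusted p = 0.0634 and 0.0528). In this order, the 4 lists had an adjusted p = 0.465, 0.480, 0.344 and 0.344 with an estimated correlation.

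Members went both ways without a list call in sulfur metabolism, where 12 of 29 genes rose, among them MET28 (1.33 ± 0.32), 6 fell, among them SAM4 (−1.75 ± 0.14), and the median was 0.06. Glycolysis genes rose in 11 and fell in 2 of 21 cases (median 0.44, camera adjusted p = 0.0542), where TDH1 stood at 1.5 ± 0.34 and the hexokinase gene HXK2 at −1.40 ± 0.41. In the pentose phosphate list 6 genes rose and 3 fell of 11, with GND2 and TKL2 (2.54 ± 0.47) up and RKI1 (−1.54 ± 0.11) down. Phospholipid genes rose in 8 and fell in 2 of 14 cases (median 0.59, camera adjusted p = 0.0688), led by the methyltransferase gene OPI3 at 2.61 ± 0.44. Lysine synthesis genes fell in 5 and rose in 1 of 8 cases (median −0.77, camera adjusted p = 0.0526). Glycerol and osmotic genes rose in 5 and fell in 1 of 11 cases (5 and 2 adjusted over the list alone), with GUT2 at 1.95 ± 0.26, and copper and zinc genes rose in 7 and fell in 1 of 15 cases (7 and 2 adjusted over the list alone), with the metallothionein gene CRS5 at 2.02 ± 0.14. The lysine list was called without replicate 2 (adjusted p = 0.0442) or 3 (0.0481), and those of alcohol dehydrogenases and glycolysis without replicate 1 (0.0275 and 0.0245) or 3 (0.0365 and 0.0451), as was the glycerol list without replicate 3 (0.0481). The phospholipid list was called with the low-power scans alone (0.0164), with values on at least 2 arrays (0.0165) and with fry (0.0396), and the pentose phosphate list without genes whose scans differ (0.0142) and with fry (0.0265). Values on at least 2 arrays also gave calls for the lists of pyrimidine synthesis (0.0162), lysine (0.0182), glycerol (0.0206), glycolysis (0.0416) and alcohol dehydrogenases (0.0482). Since values were missing there, that setting used camera's form for ranked gene statistics, so its calls may follow from the test and not only from the genes. The lysine list was also called with the low-power scans alone (0.0403), without genes whose scans differ (0.0447), with array weights (0.0427), after the position correction (0.039) and with fry (0.0178), glycolysis without genes whose scans differ (0.0209), and alcohol dehydrogenases with the high-power scans alone (0.0312). With fry, the lists of glycerol (0.0396), copper and zinc (0.0231), the vacuole (0.0238) and hypoxic genes (0.0231) were called, whereas those of multidrug resistance and iron were not.

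The remaining lists showed no call by camera. The unfolded protein response had 4 of 18 genes higher and 1 lower (median 0.12), ubiquitin 1 and 1 of 17 (median −0.11, mean 0.03), fatty acid synthesis 3 and 3 of 12 (median 0.16) and the vacuolar list 6 and 3 of 16 (median 0.15). Mitochondrial ribosomal protein genes had 5 higher and 16 lower of 61 (2 and 7 adjusted over the list alone; median −0.07). Pyrimidine synthesis had 2 higher and 5 lower of 7 (median −0.65), branched-chain amino acids 2 and 1 of 12 (median −0.05, mean 0.01) and arginine 0 and 0 of 5 (median 0.04, mean −0.01). Histones had 2 of 9 higher (1 adjusted over the list alone; median 0.26), G2/M genes 1 higher and 3 lower of 10 (1 and 2 adjusted over the list alone; median 0.04, mean −0.04) and daughter-cell genes 5 and 2 of 14 (median 0.09). Amino acid permeases had 7 higher and 2 lower of 16 (median 0.34), hypoxic genes 6 and 2 of 13 (median 0.35) and pheromone response genes 4 and 3 of 13 (median 0.33). Among mating type genes, all 3 measured alpha-specific genes fell, MF(ALPHA)2 as above, SAG1 by 1.06 ± 0.33 and STE3 by 0.94 ± 0.39. STE6, the only measured gene specific to the other mating type, stood at 0.38 ± 0.29 and did not pass the test over all genes (limma adjusted p = 0.065). As the only member, it has no adjustment over the list alone, and its unadjusted limma p was under 0.05.

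The replicates correlated across genes, which are not independent replicates, at a Pearson's r of 0.826 (1 and 2), 0.888 (1 and 3) and 0.821 (2 and 3), and the median SD of a gene was 0.22. Without replicate 1, 692 genes were higher and 594 lower. With the low-power scans alone, which left 1710 genes to test, 15 of the 33 list calls were kept, 10 were lost and 8 lists had too few genes to test. Beside those of fatty acid oxidation, nitrogen and thiamine, the lost calls were those of the citric acid cycle (median 0.25), the respiratory chain (0.25), aromatic amino acids (−0.44), multidrug resistance (0.25), iron (0.16), DNA damage (0.47) and autophagy (0.66).

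The technical comparison of the scans asks whether laser power changed the ratio. Among 1595 genes with spots valued in both scans of all 3 arrays, 29 differed (limma), 23 with a higher ratio at high power and 6 with a lower ratio. TIF2, a gene of translation initiation factor 4A, had a high minus low difference of 0.43 ± 0.03, RPL10 of 0.39 ± 0.08, the cell wall gene SCW4 of 0.38 ± 0.08 and the proton pump gene PMA1 of 0.36 ± 0.22. The 23 held further ribosomal protein genes, such as RPS8B (0.36 ± 0.13) and RPL8A (0.36 ± 0.16). RPL8A stood at −0.60 at high and −0.96 at low power. The largest difference was that of NET1, at −0.72 ± 0.04, with a mean ratio of −0.71 at high and 0.00 at low power. The median absolute difference was 0.08, and 19 of the 29 genes were also called for methanol. The difference was taken per spot after a first result from gene means, which gave 23 genes, had been seen to mix different spots of a gene. The count was 1 without centring, and 0 without replicate 2 and 13 without replicate 3.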

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

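The tests of dim spots, growth at harvest and dye for the stress genes, that of position for replicate 2 and the counts over sign patterns were chosen only after the results were seen. Spots without a gene name entered no gene or list comparison, and what they measure is unknown here. Of 288 such spots with a value on all 3 arrays, limma called 127 higher and 17 lower, with a median log2 ratio of 0.43 on the scale on which the median gene is 0. No gene can be given for them here.

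The lists of the general stress response and of the glyoxylate cycle and gluconeogenesis were higher, with medians of 1.61 and 1.36 (adjusted p = 0.344 for each with an estimated correlation). A lean of dim spots to higher ratios is argued against for the 16 stress genes with a value in all 6 scans, whose median lay 1.38 above that of all such genes (1.35, 1.47 and 1.60 on the 3 arrays). For gluconeogenesis such a lean stays open, since the values go both ways. The median of that list was 0.93 above that of spots without a gene name (0.74 on the lowest array). It was also above the highest, 1.02, of 10000 random lists of genes with as many scans. However, the 2 members with a value in all 6 scans lay 0.23 above all such genes (0.31, 0.52 and −0.17 on the 3 arrays). A difference in growth or density of the cultures at harvest, which may follow from methanol itself, stays open, since ribosomal protein genes also moved, with a median of −0.64, and no density at harvest is given in the sources used here. Dye bias and treatment cannot be told apart, because 0 arrays had the dyes swapped, and a response to methanol remains a hypothesis.

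Replicate 2 stood apart from replicates 1 and 3. The SD of the difference between replicates 1 and 2 was 1.43 times that between 1 and 3. Ratios on replicate 2 also had a wider SD over genes, 0.85 against 0.73 and 0.69 on replicates 1 and 3. A wider scale by itself raises such a difference, and its share was not tested. A trend along the corrected field of the spot number is argued against as the whole source, since after that correction the ratio was 1.37 (95% bootstrap interval 1.31 to 1.43). Trends along other fields were not tested and stay open. Fewer spots with a value on replicate 2 are also argued against as the whole source, since among the 1596 genes with a value in all 6 scans the ratio was 1.35 (1.28 to 1.42). Whether the signal of these genes was weaker on replicate 2 could not be tested without intensities. Differences between the cultures or hybridisations were not tested and stay open.

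Only 4 sign patterns of 3 arrays exist, so no share under 0.05 can be reached. The real pattern called 2180 genes, 571 of them changed at least 2-fold, and the highest other pattern called 0 of either, so that 1 pattern, the real one, gave as many. For lists the real pattern called 33 and the highest other 26, and for the difference between scans 29 and 0.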

How the results depend on the processing

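The position correction and the difference of gene means were chosen after seeing the data. No gene called in the main setting was called in the opposite direction in any alternative of the gene test, the position correction included. The difference of gene means bears only on the comparison of scans. The low-power scans alone gave 431 genes higher and 485 lower, 115 and 96 of them at least 2-fold, and 8 lists higher, with 1710 genes and 44 lists tested; of the 862 main calls tested there 838 remained. Under them the thiamine and pyridoxine list turned to a median of −0.057 (adjusted p = 0.816); the cause was not tested. At an adjusted p under 0.01, 639 genes were lower, by construction of the threshold. Without a replicate, the counts ranged from 692 to 1156 genes higher and from 594 to 1074 lower. With an estimated correlation 0 lists were higher and 0 lower, against 24 and 14 with fry. The estimate rests on the spread over 3 arrays, so the count of 0 decides neither for nor against the list calls. Genes whose ratio differs between scans numbered 1 as deposited, 5 with scale and 13 with quantile normalization, 3 with values on at least 2 arrays, 54 without genes whose scans differ by over 0.5, 60 with array weights, 23 from gene means, 1 at an adjusted p under 0.01 and 0 to 34 without a replicate; the cause was not tested. The position-corrected setting kept 2069 of 2180 calls. Of the values of named genes under all settings, 7 lost their call and 1830 did not, RPS6B among the former with robust moderation (adjusted p = 0.0587). Each array's ratio already pairs a treated with an untreated sample, so no further paired fit was run. Without intensities, limits from signal over background are unknown.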

Other observations

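The genes named in this part, the test of dim spots and the difference at chromosome ends without list members were chosen after their values were seen. Of 4 aquaporin genes tested, AQY1 rose by 2.91 ± 0.20 and AQY3 by 2.78 ± 0.23 (n = 3), while AQY2 stood at −0.22 ± 0.76 and FPS1, the glycerol channel gene, at −0.39 ± 0.26, and neither of these passed the test (limma adjusted p = 0.496 and 0.0553). ACT1, the actin gene, often used as an internal standard, stood at 0.46 ± 0.14 (limma adjusted p = 0.0191), at 0.42 without centring and at 0.46 with scale or quantile normalization. Its call was lost with the low-power scans alone (0.33, limma adjusted p = 0.0512), without replicate 1 (0.54, 0.0650) and without replicate 3 (0.45, 0.0973). The desaturase gene OLE1 rose by 0.91 ± 0.05.

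Genes near chromosome ends had higher ratios. Among the 10 protein-coding genes nearest to each end of the 16 chromosomes, 215 were measured, and their median was 0.44 against −0.04 for the other 4121 genes, a difference of 0.42, 0.60 and 0.39 on replicates 1, 2 and 3. Of the 215, 50.7% were called higher, against 24.8% of the others. Signal shared within near-identical families and a trend along the corrected field of the spot number are argued against as the whole cause. The difference, taken from genes with as many scans, was 0.27 without such families and uncharacterised genes (two-sided permutation p = 0.00029). After the position correction it was 0.48 (permutation p = 1e-05, the smallest that 100000 permutations can give). Both permutations run over genes, which are not independent. Trends along other fields of the spot number were not tested. A lean of dim spots to higher ratios stays open, since the difference was 0.14 among genes with a value in all 6 scans (67 near ends, permutation p = 0.116) and 0.65, 0.74 and 0.37 among those with 3, 4 and 5 scans, while other genes with 3 scans had a median of −0.03 and spots without a gene name one of 0.43, about that of the end genes.

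Without the genes of lists called higher, the difference for genes near chromosome ends was 0.35 over 162 end genes, and without both these and the families it was 0.20 over 79 (two-sided permutation p = 0.0114). Of the 162, 66 were called higher, among them DSF1 (2.87 ± 0.23), which belongs to the families left out, CHA1 (1.5 ± 0.14) and YPS5 (1.38 ± 0.04), and 25 lower, among them SAM4 (−1.75 ± 0.14), IMD2 (−1.58 ± 0.17) and DLD3 (−1.49 ± 0.14). Which of the genes lie in silenced regions was not tested.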
